A study of Mus musculus with 20 samples.

How the data were processed

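Liver RNA from 20 individual mice was measured by RNA sequencing in 4 groups of 5: control mice and mice given anti-CD40, each with no antibiotics or with antibiotics (ABX). Group, antibiotic status and the plate position of each library were taken from the labels. Per the labels' protocols, RNA was extracted with trizol from snap-frozen liver sections and made into Illumina libraries. The dose and timing of the antibody, whether it activates or blocks CD40, the antibiotics used and the library kit are not given in the sources used here. The mice were numbered without any number shared between groups, so no pairing was possible.

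Each library has 1 deposited table of whole-number counts per feature. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38 and aligned with HISAT2 2.1.0, and the genome build named is mm10. Per the file headers, the authors counted fragments with featureCounts 1.5.0-p2 in paired mode over exons grouped by gene identifier, with no strand option. The annotation named in those headers is the human GRCh38 annotation of Ensembl release 93. The deposited counts are not normalized.

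The mouse alignments were therefore counted at human exon coordinates, and the deposited human gene identifiers carry no gene meaning here. This was tested on the files. The 3576 features on human chromosomes 20, 21 and 22, which the mouse does not have, held 0 counts in all libraries. The 5883 nuclear features that lie past the last mouse gene of a chromosome held 36 of 123867788 counts. Read as mm10 positions, features over mouse exons held 99.46% of counts, against 21.47% to 76.87% when all coordinates were shifted by 10000, 1000000 or 3000000 bp in either direction.

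Feature coordinates were read as mm10 intervals and intersected with bedtools 2.31.1 with the exons of the mouse GENCODE M21 annotation, which is on the same build and holds 55536 genes. A feature was attributed to a mouse gene when its intervals lay over the exons of exactly 1 gene by at least 50 bp. This rule was set after the files had been examined and before any groups were compared. Of 58395 features, 18918 had counts; 8331 lay over exactly 1 mouse gene and 7463 were attributed, to 5552 genes, of which 4217 had counts. Features over several genes held 52.34% of counts and were left out of the gene tests, because the deposited counts do not tell their genes apart. The mouse gene's symbol, taken from the annotation, names the sum of its attributed features. That sum measures a part of the gene: the median tested gene was measured over 372 bp, or 7.6% of its exon length. Counts do not use strand, so overlapping antisense transcripts cannot be separated, and near-identical copies such as Tgtp1 and Tgtp2 can share reads.

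The attribution was checked on the 446 tested genes covered by 2 features counted separately. The log2 fold changes of the 2 features correlated across genes with r = 0.866 for anti-CD40 without ABX, 0.902 for anti-CD40 with ABX and 0.443 for ABX in control mice; the largest r of 1000 shuffles of the partners was 0.159, 0.135 and 0.149. Where both features were called, they moved the same way for 192 of 200, 178 of 182 and 10 of 10 genes, in the same order. The other genes of the first 2 sets had features moving in opposite ways, so 1 part of a gene need not follow another. The correlations are across genes, which are not independent replicates.

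Totals over all features served as library sizes and ranged from 5053014 to 7618736 counted fragments, with a median of 6199078. Attributed genes held 1982666 to 4048783 counts per library. Genes were filtered with filterByExpr, which left 2200, of which 2025 were protein-coding. The main test was edgeR 4.0.16 in R 4.3.3: TMM scaling, robust dispersions and a robust quasi-likelihood F-test, two-sided, with 1 fit of all 20 libraries and a mean per group. Adjusted p-values are Benjamini-Hochberg values over the 2200 genes, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 16.7%. The 5 comparisons were anti-CD40 against control without ABX and with ABX, the difference between those effects, and ABX against no ABX in control and in anti-CD40 mice. Levels are TMM-normalised counts per 1000000 (CPM), and plots use log2 CPM with a prior count of 2.

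Before the data were examined, 37 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule takes, per comparison, the 6 called genes with the largest change in each direction and a mean of at least 1 CPM, up to 4 members of each described list by smallest p, and 6 genes in every comparison: Cd40, Saa1, Ifng, Tnf, Il6 and Cyp7a1. The lists hold 607 members, of which 67 were measured. Limma 3.58.1 camera, with its preset correlation of 0.01, tested whether a list differed from other genes, with Benjamini-Hochberg adjustment over the 14 lists with at least 3 measured members. That minimum, and the choice of lists whose members are named, were set after the data were examined. Camera with an estimated correlation and fry were the alternatives. Where a group held 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group; where it held 1 to 3 counts, the ratio carries a 95% counting interval. Those intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

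Alternatives for the counts of calls were RLE, upper-quartile and library-total scaling, no filter on low counts, at least 1 CPM in at least 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, plate column as a term, a fit of only the 2 groups compared, column 3 of the plate alone for the control mice, and leaving out each library in turn. Chosen after the data were seen were a stricter attribution (at least 100 bp and no other gene within 100 bp), a wider one, the deposited features with no attribution, and all libraries but those of anti-CD40 mice 14, 15, 19 and 20. Replicates were compared before averaging. The chi-square over its degrees of freedom for replicates of a group ranged from 5.25 to 92.46, so no library was a copy of another of its group. Libraries of different groups were not compared in this way. The steps were tested on simulated counts with 200 changed genes. In the simulation of anti-CD40 without ABX on 2070 genes, 66.1%, 86% and 98.6% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. Of its calls, 4.2% were unchanged genes. Only those 200 genes changed, up or down at random, with no plate column effect. These rates therefore do not test the scaling or the error rate where most genes change, as in the anti-CD40 comparisons. Some genes of the lists are not reported here; they stayed in all counts of calls and list tests. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.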

Results

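Liver transcripts were counted in 20 mice, 5 in each of 4 groups. Control mice and mice given anti-CD40, an antibody to CD40, a receptor of the tumour necrosis factor family on antigen-presenting cells, were each studied with no antibiotics and with antibiotics (ABX). Counted fragments per library ranged from 6196703 to 7618736 in control mice without ABX, from 6201453 to 7282519 in control mice with ABX, from 5391794 to 6211642 in anti-CD40 mice without ABX and from 5053014 to 5874749 in anti-CD40 mice with ABX. Mitochondrial transcripts took 28.5% ± 3.53 (SD, n = 5) of counts in control mice without ABX and 32.2% ± 2.16 with ABX. In anti-CD40 mice they took 24.8% ± 0.790 without ABX and 23.3% ± 1.86 with ABX. Albumin (Alb) took 15.1% ± 0.690 and 17.6% ± 1.78 of counts in control mice without and with ABX, and 6.75% ± 0.600 and 8.88% ± 0.810 in anti-CD40 mice. Levels below are normalised counts per 1000000 (CPM, mean ± SD, n = 5), and changes are log2 fold changes ± SE from edgeR with Benjamini-Hochberg adjusted p.

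The counts had been made at human exon coordinates on mouse mm10 alignments, so each mouse gene was measured only over the exon parts that those coordinates happen to cover. Fas, for example, was measured over 251 bp of exon between positions 34300075 and 34327772 of chromosome 19, and Alb over 474 bp between 90460897 and 90474699 of chromosome 5. Tgtp2 was measured over 692 bp on chromosome 11 (49057194 to 49059112) and Cyp3a11 over 163 bp on chromosome 5 (145858721 to 145858883). No interval could be attributed to Cd40, Saa1, Ifng, Tnf, Il6 or Cyp7a1, which were therefore not analysed here.

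**Figure D1:**
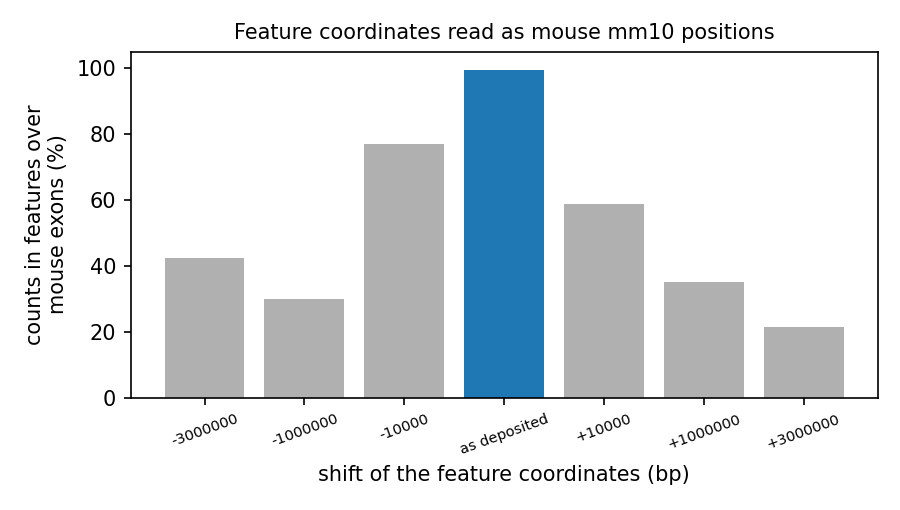
Share of all counts (y axis, percent) held by features that lie over mouse exons when the deposited coordinates are read as mm10 positions, as deposited and after shifts in bp (x axis). The share was 99.46% as deposited and 21.47% to 76.87% after the 6 shifts.

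The first comparison asked what anti-CD40 did to the liver of mice without ABX. Interferon-response, CD40-signalling and antigen-presentation genes rose, and drug-metabolising and fat-metabolising enzymes fell. Tgtp2, an interferon-inducible GTPase, rose from 5.5 ± 0.972 to 178 ± 4.94 CPM (log2 fold change 5.00 ± 0.14, adjusted p = 5.9e-19), and Cyp2c50, a drug-metabolising cytochrome P450, fell from 640.1 ± 73.9 to 51.3 ± 7.14 CPM (-3.64 ± 0.12, adjusted p = 5.77e-18). Of 2200 genes tested, 1333 were called, 700 higher and 633 lower, and 591 changed at least 2-fold. With library totals in place of TMM scaling the calls split into 932 higher and 405 lower, 69.7% higher against 52.5%, because that scaling moved the median of all genes from 0.03 to 0.27. All 4 measured members of the interferon gamma response list rose (adjusted p = 6.94e-05 by camera, and adjusted p = 0.0532 with an estimated correlation). Besides Tgtp2 these included Tgtp1, its near-identical copy (5.66 ± 0.20), and the GTPase Irgm2 (2.58 ± 0.19). All 3 measured members of the CD40 and its signalling list rose (adjusted p = 0.00223 by camera, and adjusted p = 0.0532 with an estimated correlation). The death receptor Fas rose from 14.2 ± 2.43 to 59.6 ± 7.88 CPM (2.07 ± 0.11), Nfkb2, a subunit of noncanonical NF-kB, by 3.38 ± 0.21 over 57 bp, and the NF-kB inhibitor Nfkbia by 2.46 ± 0.16. All 3 measured members of the cell death list rose (adjusted p = 0.013 by camera, and adjusted p = 0.0532 with an estimated correlation), among them Fas and the kinase Ripk3 (1.55 ± 0.21). All 3 measured members of the microbial product sensing list rose (adjusted p = 0.0415 by camera, and adjusted p = 0.218 with an estimated correlation), among them the inflammasome sensor Nlrp3 (3.72 ± 0.40) and the peptidoglycan sensor Nod1 (1.38 ± 0.16). Both measured members of the type I interferon response list rose, Rtp4 by 3.24 ± 0.24 and the RNA sensor Ifih1 by 1.07 ± 0.13, as did both measured members of the MHC class II list, H2-Aa (from 52.7 ± 12.3 to 337 ± 41.8 CPM, 2.68 ± 0.19) and H2-DMb1 (2.63 ± 0.16). The single measured member of the acute phase list, ceruloplasmin (Cp), rose from 1089 ± 307 to 5413 ± 773 CPM (2.31 ± 0.14). The single measured member of the cytokines list, Il33, rose by 1.65 ± 0.59 (adjusted p = 0.0206). That call was lost without mouse 10, 16 or 17, with values of 1.42, 1.38 and 1.40, and with no filter on low counts. With plate column as a term the value was 3.31. In this comparison, values with that term rest on mouse 16 against control mice 9 and 10, which share plate column 4. Of 3 measured members of the chemokines list, 1 rose, 1 fell and 1 was not called; adjusted over the list alone, 2 rose and 1 fell. The macrophage chemokine gene Ccl3 had 3 counts over the 5 control mice and 295 over the 5 anti-CD40 mice, a ratio of 96.1 (95% counting interval 32.6 to 469); its fitted log2 value was 6.33, and 5.44 without mouse 18. The eosinophil chemokine Ccl24 fell by 2.16 ± 0.28 on the log2 scale. For every other list, the counts of calls adjusted over the list alone were those over all genes.

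Markers of the liver's other cell types moved in different directions. All 3 measured members of the T cell markers list rose (adjusted p = 0.149 by camera, and adjusted p = 0.374 with an estimated correlation), among them Cd8b1 from 0.343 ± 0.244 to 2.33 ± 0.999 CPM (2.70 ± 0.52) and Cd8a by 2.52 ± 0.51, both at low levels. Of 3 measured monocyte and macrophage markers, 2 rose and 1 fell. Lyz2, lysozyme, rose from 123 ± 44.0 to 612 ± 302 CPM (2.32 ± 0.40) and Ms4a7 by 2.25 ± 0.30, whereas Adgre1, which encodes the macrophage antigen F4/80, fell from 21.9 ± 9.31 to 3.84 ± 2.29 CPM (-2.50 ± 0.38). Of 3 measured sinusoidal endothelial markers, 1 fell and 2 were not called. The hyaluronan receptor Stab2 fell from 46.0 ± 5.73 to 4.50 ± 1.94 CPM (-3.36 ± 0.31, and -2.19 with the wider attribution). Pecam1, a general endothelial adhesion molecule, stood at -0.19 ± 0.51 (adjusted p = 0.777), at 0.02 without mouse 19 or mouse 20, at 0.09 with library totals, at 0.60 with plate column as a term and at 0.33 without mice 14, 15, 19 and 20. Those 4 mice had the lowest Pecam1 levels of the 10 anti-CD40 mice, which ranged from 7.4 to 76.9 CPM, and without them 1231 genes were called. Of 2 measured cholangiocyte markers, the transcription factor Sox9 rose by 3.05 ± 0.25 and Pkhd1 fell by 1.18 ± 0.34 on the log2 scale. The single measured adipose marker, Cfd, fell from 10.6 ± 11.1 to 0.803 ± 0.459 CPM (-3.70 ± 0.92, and -2.84 without control mouse 8). The single measured members of the B cell, plasma cell, Kupffer cell and erythroid lists were not called by edgeR at an adjusted p under 0.05. Neither were both measured members of the stellate cell and matrix list and all 3 of the proliferation list. For the Kupffer cell marker, Marco, control mouse 8 stood at 6.55 log2 CPM. Control mice 6, 7, 9 and 10 stood at 3.3 to 4.09, and the anti-CD40 mice at 5.28 to 7.05. Of the lists of NK cell, cytotoxic effector, dendritic cell, neutrophil, pancreas, skeletal muscle, cholesterol synthesis, and endoplasmic reticulum and amino acid stress genes, 0 members were measured.

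Enzymes of hepatocyte metabolism were mostly lower. All 4 measured members of the drug metabolism list fell (adjusted p = 7.91e-05 by camera, and adjusted p = 0.0606 with an estimated correlation). Cyp2c29 fell from 689.8 ± 124 to 34.9 ± 11.9 CPM (-4.31 ± 0.22), Cyp3a11, a main enzyme of drug oxidation, from 2763 ± 797 to 530.0 ± 153 CPM (-2.38 ± 0.24), and Aldh1a1, a retinaldehyde dehydrogenase, by 1.79 ± 0.12 on the log2 scale. All 3 measured members of the fatty acid synthesis list fell (adjusted p = 0.0193 by camera, and adjusted p = 0.197 with an estimated correlation), with the desaturases Scd1 at -2.21 ± 0.24 and Fads2 at -1.24 ± 0.14. Both measured members of the fatty acid oxidation and PPAR alpha list fell, Ehhadh, a peroxisomal enzyme, by 1.90 ± 0.17 and Acadvl by 0.70 ± 0.08 on the log2 scale. Of 3 measured members of the bile acid synthesis and transport list, 2 fell and 1 was not called (adjusted p = 0.053 by camera). Akr1d1, the steroid reductase of bile acid synthesis, fell from 215 ± 41.9 to 15.6 ± 4.18 CPM (-3.78 ± 0.17). Of 3 measured members of the gluconeogenesis and glycolysis list, 2 fell and 1 rose. Glycogen phosphorylase (Pygl, -2.10 ± 0.11) fell and pyruvate carboxylase (Pcx) rose from 502 ± 103 to 1607 ± 282 CPM (1.68 ± 0.12). Both measured urea cycle members fell, among them Cps1, the rate-limiting enzyme, from 3634 ± 413 to 737 ± 61.2 CPM (-2.30 ± 0.11). Of 5 measured members of the hepatocyte identity list, 2 rose and 3 fell, with Alb at -1.39 ± 0.13, the transcription factor Foxa2 at -1.08 ± 0.29 and the receptor Fgfr4 at 0.74 ± 0.11. The single measured member of the male and female biased list, Serpina1e, fell by 1.53 ± 0.16 on the log2 scale, and that of the circadian clock list, Per1, rose from 16.4 ± 2.43 to 33.6 ± 4.89 CPM (1.04 ± 0.22).

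Among the largest changes, Ly6i had 1 count over the control mice and 603 over the anti-CD40 mice. Myo16, with 0 counts in control mice, was at least 36.5-fold higher. The serine protease inhibitor Serpina3i rose from 0.819 ± 0.330 to 113 ± 10.9 CPM (7.08 ± 0.24, adjusted p = 4.31e-16) and the cystine transporter Slc7a11 from 0.255 ± 0.334 to 30.4 ± 16.7 CPM (6.81 ± 0.74, and 7.80 without mouse 7). Pitx3 fell from 49.1 ± 23.6 to 0.411 ± 0.334 CPM (-6.88 ± 0.69) and the mannose receptor Mrc1 from 16.1 ± 3.63 to 0.306 ± 0.321 CPM (-5.63 ± 0.45, and -6.29 without mouse 16). Among the called genes named here, the groups overlapped for Il33, Pkhd1 and Asgr1. The groups lay largely in different plate columns, and with plate column as a term 735 genes were called, 721 of them among the 1333, while Ly96, Cd8a, Pkhd1, Cfd, Foxa2, Asgr1 and Per1 were not. With library totals the calls of Asgr1 (-0.29 ± 0.10 with TMM, -0.06 with totals) and Slc25a15 (-0.46 ± 0.10, -0.21) were lost.

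**Figure D2:**
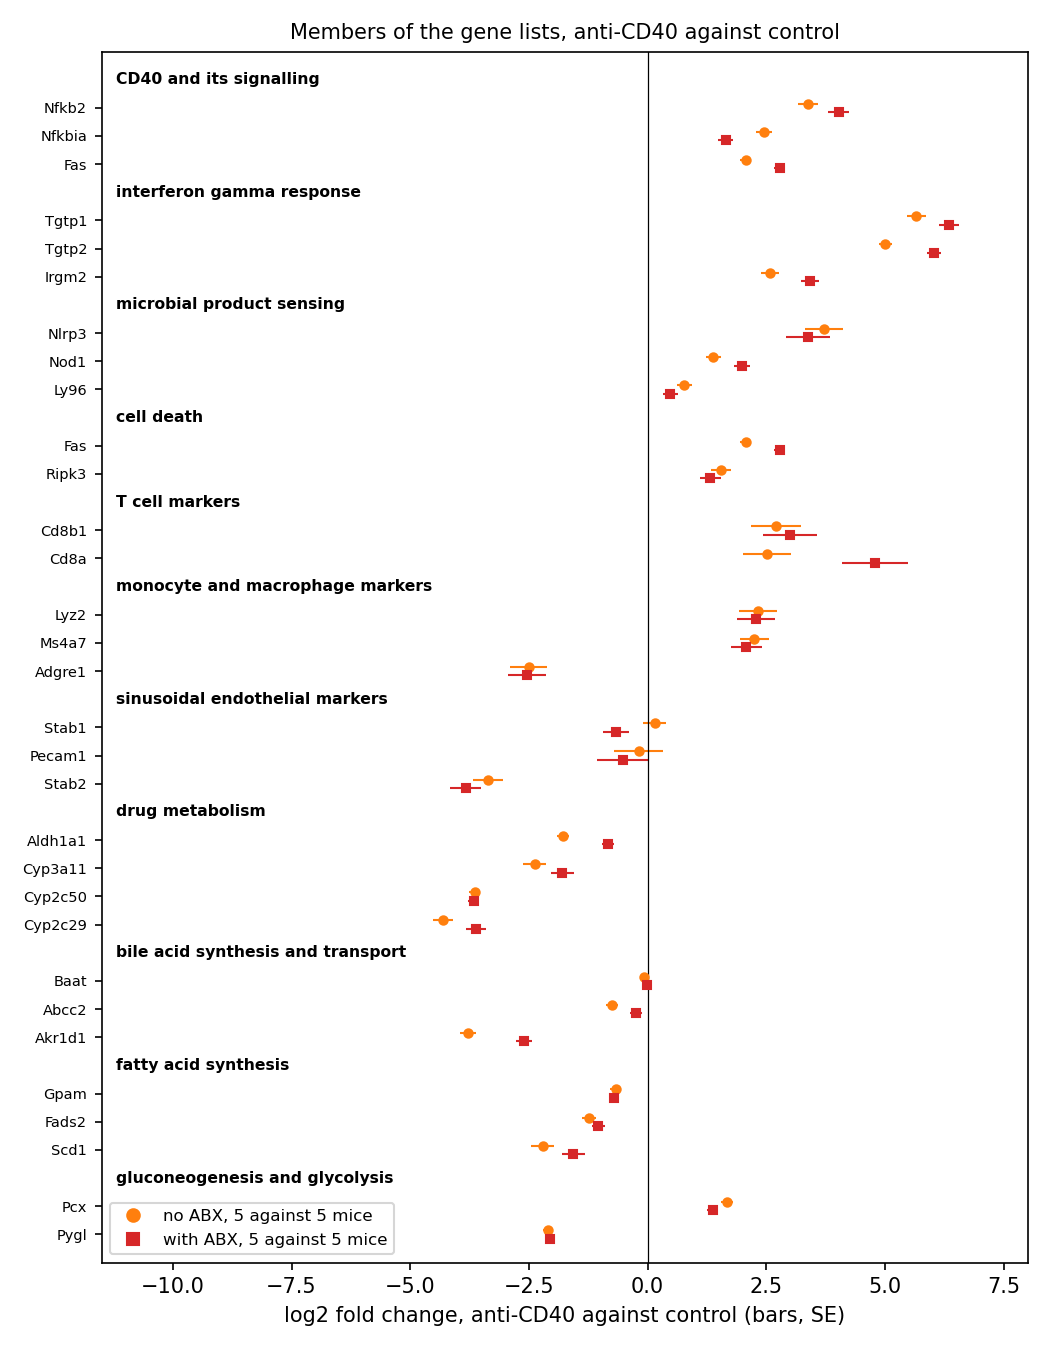
Log2 fold change of anti-CD40 against control (x axis) for reported members of the gene lists with at least 3 measured members that are described here (y axis), without ABX (circles) and with ABX (squares), 5 against 5 mice each, with bars for the SE. Tgtp1 lies at 5.66 and 6.35, Cyp2c50 lies at -3.64 and -3.66, and the value of Cd8a with ABX rests on 2 control counts.

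The same question was asked in mice given ABX. Interferon-response and CD40-signalling genes again rose with anti-CD40 and drug-metabolising enzymes fell. Tgtp2 rose from 6.19 ± 1.12 to 405 ± 79.3 CPM (log2 fold change 6.03 ± 0.14, adjusted p = 1.32e-20) and Cyp2c50 fell from 1052 ± 11.6 to 83.0 ± 13.3 CPM (-3.66 ± 0.11, adjusted p = 4.29e-18). Of 2200 genes, 1133 were called, 585 higher and 548 lower, and 507 changed at least 2-fold. With library totals there were 1347 calls, of which 76.8% were higher against 51.6%, and the median of all genes moved from 0.02 to 0.37. The 2 anti-CD40 comparisons share no libraries; 913 genes were called the same way in both and 8 in opposite ways. Of the 913, 475 were higher in both, against 186.1 for independent lists, and 438 lower in both, against 157.7. Where a gene was called in only 1 of them, the difference itself was tested in the third comparison. All 4 measured members of the interferon gamma response list rose (adjusted p = 2.51e-06 by camera, and adjusted p = 0.0314 with an estimated correlation), among them Irgm2 by 3.42 ± 0.19. All 3 of the CD40 and its signalling list rose (adjusted p = 0.00101 by camera, and adjusted p = 0.0314 with an estimated correlation), Fas from 10.7 ± 0.569 to 73.8 ± 7.45 CPM (2.78 ± 0.12), Nfkb2 by 4.02 ± 0.22 and Nfkbia by 1.65 ± 0.16. All 3 of the cell death list rose (adjusted p = 0.00452 by camera, and adjusted p = 0.0314 with an estimated correlation), with Ripk3 at 1.32 ± 0.23. All 3 of the microbial product sensing list rose (adjusted p = 0.0496 by camera, and adjusted p = 0.242 with an estimated correlation), Nlrp3 by 3.38 ± 0.47 and Nod1 by 1.99 ± 0.16. Both measured type I interferon response members rose, Rtp4 by 3.89 ± 0.25 and Ifih1 by 1.42 ± 0.13, and both MHC class II members, H2-Aa by 2.64 ± 0.19 and H2-DMb1 by 2.31 ± 0.15. Cp, of the acute phase list, rose by 2.07 ± 0.14, and the measured cytokine was not called. Of 3 chemokines, Ccl3 rose, Ccl24 fell by 1.21 ± 0.27 on the log2 scale and 1 was not called. All 3 T cell markers rose (adjusted p = 0.0496 by camera, and adjusted p = 0.242 with an estimated correlation). Cd8a had 2 counts over the control mice and 77 over the anti-CD40 mice, a ratio of 35.3 (95% counting interval 9.45 to 297). The measured B cell marker was not called over all genes and was higher adjusted over the list alone, and the measured plasma cell marker, the immunoglobulin constant gene Ighm, rose by 0.71 ± 0.16.

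Of 3 monocyte and macrophage markers, Lyz2 (2.28 ± 0.40) and Ms4a7 (2.08 ± 0.33) rose and Adgre1 (-2.54 ± 0.39) fell. The measured Kupffer cell marker, the scavenger receptor Marco, was called at 1.72 ± 0.64 (adjusted p = 0.0344). That call was lost without any 1 of mice 1, 3, 4, 5, 12, 13 and 15, with values of 1.52 to 1.73. It was also lost with no filter and without mice 14, 15, 19 and 20. With plate column as a term the value was 3.37. That term takes the difference between columns 4 and 3 from control mice 9 and 10 against 6, 7 and 8. For Marco, mouse 8 stood at 6.55 log2 CPM and the others of these at 3.3 to 4.09, so 3.37 leans on mouse 8. Of 3 sinusoidal endothelial markers 2 fell, with Stab2 from 49.1 ± 5.54 to 3.53 ± 2.86 CPM (-3.83 ± 0.33, and -2.39 with the wider attribution) and Stab1 at -0.67 ± 0.27 (adjusted p = 0.041). The Stab1 call was lost without any 1 of mice 3, 4, 5, 13, 14 and 15, with values of -0.69 to -0.51, with library totals (-0.32), no filter or plate column as a term, and without mice 14, 15, 19 and 20. Both stellate cell and matrix genes fell, the collagen Col3a1 from 118 ± 43.1 to 24.4 ± 22.9 CPM (-2.29 ± 0.62, adjusted p = 0.00532) and Lum by 1.5 ± 0.53 on the log2 scale, a call that was lost without mouse 11 (-1.32), with library totals and without mice 14, 15, 19 and 20. Without those 4 mice 1025 genes were called. Of 2 cholangiocyte markers Sox9 rose by 2.43 ± 0.29 and 1 was not called, and the measured erythroid and adipose markers were not called. All 4 drug metabolism genes fell (adjusted p = 0.000154 by camera, and adjusted p = 0.0724 with an estimated correlation), with Cyp2c29 at -3.62 ± 0.21 and Cyp3a11 at -1.79 ± 0.24. All 3 fatty acid synthesis genes fell (adjusted p = 0.0232 by camera, and adjusted p = 0.214 with an estimated correlation), with Scd1 at -1.56 ± 0.23, as did both fatty acid oxidation genes, with Ehhadh at -1.42 ± 0.16 and Acadvl at -0.46 ± 0.08, a call that was lost with library totals (-0.11). Of 3 bile acid genes, Akr1d1 fell from 289 ± 23.2 to 47.4 ± 9.51 CPM (-2.60 ± 0.16) and 2 were not called. Of 3 gluconeogenesis and glycolysis genes 2 fell and 1 rose: Pygl (-2.06 ± 0.11) fell and Pcx (1.37 ± 0.12) rose. Both urea cycle genes fell, with Cps1 at -1.85 ± 0.11. Of 5 hepatocyte identity genes 2 rose, 2 fell and 1 was not called, with Alb at -1.34 ± 0.13 and Fgfr4 at 0.55 ± 0.12 (0.90 with library totals). Asgr1 was called at -0.25 ± 0.09, a call that was lost without any 1 of mice 3, 4, 5, 11 and 13, with values of -0.24 to -0.20, and that turned with library totals (0.10). Of 3 proliferation genes 1 rose, 1 fell and 1 was not called. The gene that rose, Kif11 (1.03 ± 0.37), was not called without mouse 4, 5, 13 or 14, with values of 0.87 to 0.93, with no filter, or without mice 14, 15, 19 and 20. The gene that fell, Ccnb2 (-1.09 ± 0.29), was not called with library totals (-0.73) or with plate column as a term (-0.70). Per1 fell from 41.5 ± 15.4 to 17.5 ± 3.84 CPM (-1.24 ± 0.22), and Serpina1e fell by 1.23 ± 0.16 on the log2 scale (-0.80 with plate column as a term). Among the largest changes, Ly6i, with 0 counts in control mice, was at least 115-fold higher, Serpina3i rose from 0.600 ± 0.565 to 59.6 ± 10.1 CPM (6.58 ± 0.27), and Pitx3 (-6.97 ± 0.78), Mrc1 (-4.76 ± 0.41, and -5.43 without mouse 12) and the matrix protein Fbln5 (-4.62 ± 0.43) fell. Among the called genes named here, the groups overlapped for Ly96, Stab1, Asgr1, Ccnb2, Kif11 and Per1. All 5 control mice with ABX lay in plate column 3 and all 5 anti-CD40 mice with ABX in column 4. The difference between these columns can be estimated only from the control mice without ABX, 3 in column 3 and 2 in column 4. With plate column as a term 690 genes were called, 676 of them among the 1133. Ly6i, Ccl3, Ccl24, Ly96, Cd8a, Stab1, Col3a1, Lum, Asgr1, Ccnb2 and Kif11 were not.

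The third comparison asked whether the anti-CD40 effect differed between mice with and without ABX. Among genes called for this difference, Tgtp2 and Ripk2 rose further with anti-CD40 in ABX mice, and others, such as Smox, changed less. Ripk2, the kinase downstream of the NOD receptors, rose from 10.5 ± 0.967 to 68.0 ± 19.8 CPM without ABX and from 9.65 ± 1.59 to 199.8 ± 30.3 CPM with ABX (log2 difference of effects 1.68 ± 0.25, adjusted p = 0.000669). Smox, spermine oxidase, reached 146 ± 98.7 CPM in anti-CD40 mice without ABX and 25.7 ± 4.40 with ABX, against 17.1 ± 2.24 and 14.1 ± 2.16 in control mice (-2.22 ± 0.51, adjusted p = 0.0153). Of 2200 genes, 166 were called, 96 with a higher and 70 with a lower effect in ABX mice, and 51 differed at least 2-fold. With library totals 80.3% of 137 calls were higher, against 57.8%, and the median of all genes moved by 0.10. Of the 166, 106 had a smaller anti-CD40 effect with ABX and 60 a larger one, and 139 were called for anti-CD40 without ABX and 107 with ABX. Of 1471 genes called for the mean anti-CD40 effect, 870 had a smaller effect with ABX, with a median ratio of the log2 effects of 0.877; fry tests of these genes signed by direction and of the higher ones alone did not pass 0.05, while that of the lower ones alone did, before any adjustment for the 3 tests. Of 4 interferon gamma response genes, Tgtp2 was called (1.02 ± 0.20, adjusted p = 0.00348) and 3 were not, and 4 were higher adjusted over the list alone (adjusted p = 0.00701 by camera, and adjusted p = 0.487 with an estimated correlation). Fas, of the CD40 and its signalling and cell death lists, was also higher (0.72 ± 0.16, adjusted p = 0.00962). Nfkbia was lower (-0.81 ± 0.22, adjusted p = 0.0322), a call that was lost without any 1 of 12 mice (mice 2, 3, 4, 5, 8, 9, 10, 11, 13, 14, 16, 18), with values of -0.80 to -0.72, with library totals and with no filter. The third CD40 member was not called, and neither were 2 of 3 cell death genes, of which 1 more was higher adjusted over the list alone. Of 4 drug metabolism genes, the fall of Aldh1a1 was smaller with ABX (0.95 ± 0.17, adjusted p = 0.00195) and 3 were not called, with 2 higher adjusted over the list alone. Of 3 bile acid genes, the fall of Akr1d1 was smaller (1.18 ± 0.22, adjusted p = 0.00376) and 2 were not called, with 2 higher adjusted over the list alone. The 3 microbial product sensing genes were not called by edgeR, with 1 higher adjusted over the list alone; their median, mean and test differ in sign, as do those of the chemokines. Per1 moved in opposite directions, rising without ABX and falling with ABX (-2.28 ± 0.31, adjusted p = 5e-04). So did the group means of the kinase Rps6ka2 (-2.87 ± 0.58, adjusted p = 0.00482). Its rise without ABX rested on mice 16, 17 and 18, at 2.53, 3.57 and 3.59 log2 CPM. Mice 19 and 20 stood at 1.12 and 1.66, against 1.32 to 1.65 in control mice without ABX. The monocarboxylate transporter Slc16a12 fell from 23.5 ± 3.94 to 7.33 ± 1.58 CPM without ABX and stood at 18.8 ± 5.72 and 15.4 ± 2.65 CPM with ABX (1.39 ± 0.26, adjusted p = 0.00279). Adamtsl2 fell further with ABX (-1.99 ± 0.47, adjusted p = 0.0133), and the potassium channel gene Kcna2 rose with ABX from 6.60 ± 0.672 to 21.3 ± 4.31 CPM (1.5 ± 0.31, adjusted p = 0.00525). With plate column as a term, mouse 16 alone stands for anti-CD40 without ABX, and mice 6, 7 and 8 for control without ABX. None of the genes named here then kept a call, which the loss of mice or plate column could give. DESeq2 and limma-voom, without that term, called 201 and 232. Without mouse 4, 5, 10, 14 or 18 there were 109, 110, 104, 88 and 94 calls, and without mice 14, 15, 19 and 20 there were 79.

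**Figure D3:**
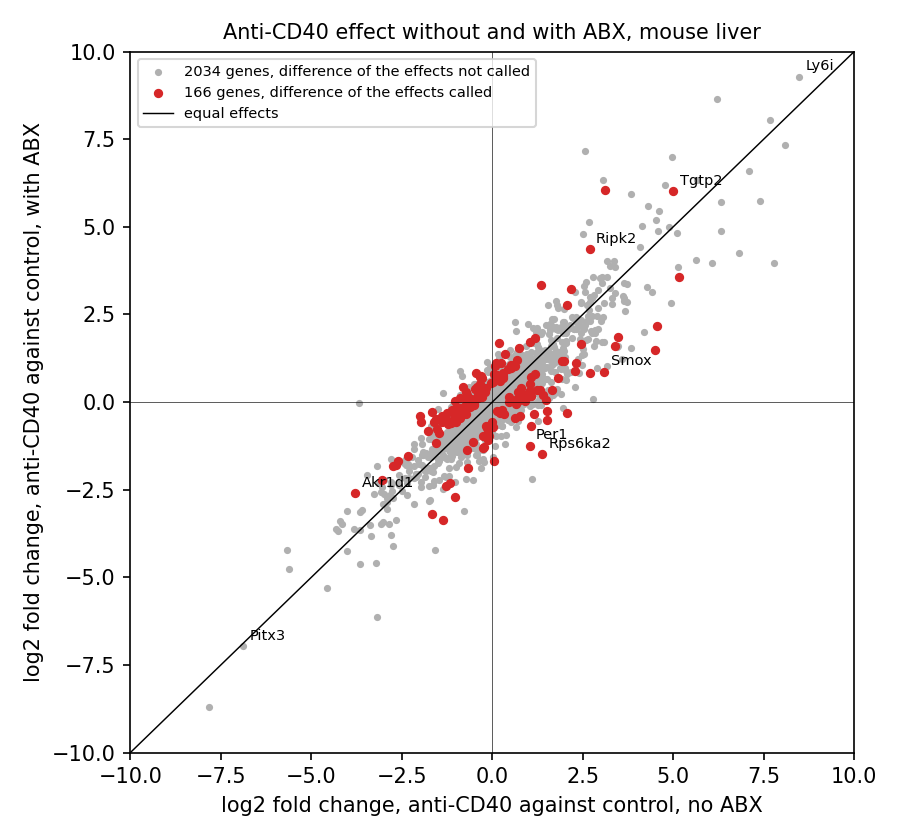
Log2 fold change of anti-CD40 against control for 2200 genes, without ABX (x axis) and with ABX (y axis), 5 against 5 mice each; red points are the 166 genes called for the difference of the effects, grey points are the other genes, and the line marks equal effects. The effects correlated across genes with Pearson r = 0.893 and Spearman rho = 0.838, genes not being independent replicates, and the position of Ly6i rests on at most 1 control count per group.

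The fourth comparison asked what ABX did in control mice. Drug-metabolising cytochromes, the clock gene Per1 and the NF-kB inhibitor gene Nfkbia were among those that changed. Cyp3a11 fell from 2763 ± 797 to 614 ± 173 CPM (log2 fold change -2.17 ± 0.24, adjusted p = 6.1e-05), while Cyp2c50 rose from 640.1 ± 73.9 to 1052 ± 11.6 CPM (0.72 ± 0.10, adjusted p = 0.000241). Per1 rose from 16.4 ± 2.43 to 41.5 ± 15.4 CPM (1.34 ± 0.22, adjusted p = 0.00174). Of 2200 genes, 147 were called, 76 higher and 71 lower, and 27 changed at least 2-fold. The share of higher calls was 51.7%, but 20.1% of 174 calls with library totals, which moved the median of all genes to -0.14, and 66.9% of 172 with upper-quartile scaling. Of 4 drug metabolism genes 1 rose, 1 fell and 2 were not called. Of 3 CD40 and its signalling genes, Nfkbia rose from 50.6 ± 2.82 to 94.7 ± 25.3 CPM (0.90 ± 0.16, adjusted p = 0.00229), Fas, also of the cell death list, fell from 14.2 ± 2.43 to 10.7 ± 0.569 CPM (-0.41 ± 0.12, adjusted p = 0.046), and 1 was not called. The Fas call was lost with RLE or upper-quartile scaling, no filter, DESeq2, limma-voom, a fit of the 2 groups or without mice 14, 15, 19 and 20, and without any 1 of 15 mice (mice 1, 2, 3, 4, 5, 6, 8, 9, 10, 11, 13, 14, 15, 16, 19), with values of -0.44 to -0.31. By camera 0 of the 14 tested lists were called, with 1 at an unadjusted p under 0.05, and 0 were called with an estimated correlation or by fry. The median, mean and test differ in sign for the CD40 and its signalling, hepatocyte identity, fatty acid synthesis and chemokines lists. Among the largest changes, Clic5, a chloride intracellular channel protein, rose from 6.98 ± 2.15 to 19.9 ± 8.02 CPM (1.52 ± 0.27, adjusted p = 0.00229) and the glutathione peroxidase Gpx6 from 1.44 ± 0.854 to 4.97 ± 1.01 CPM (1.76 ± 0.42). The transcription factor Tbx3 fell from 87.4 ± 22.3 to 28.4 ± 13.5 CPM (-1.63 ± 0.28, adjusted p = 0.00229). The groups overlapped for Per1 and Nfkbia. Plate column 3 held 8 of the 10 control mice, and within it 44 genes were called, 39 of them among the 147 and without Clic5, Per1, Tbx3, Nfkbia and Fas. With plate column as a term 77 were called, 74 of them among the 147 and without Fas. That term compares the same 8 mice of column 3, with a spread estimated from all groups, so it is not a separate check. Without mouse 4 or mouse 10 there were 90 and 89 calls.

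The fifth comparison asked what ABX did in anti-CD40 mice. Interferon gamma response genes and several metabolic enzymes were higher with ABX, and Smox and other genes raised by anti-CD40 were lower. Tgtp2 rose from 178 ± 4.94 to 405 ± 79.3 CPM (log2 fold change 1.18 ± 0.11, adjusted p = 1.69e-07) and Akr1d1 from 15.6 ± 4.18 to 47.4 ± 9.51 CPM (1.60 ± 0.17, adjusted p = 2.7e-06), while Cyp3a11 fell from 530.0 ± 153 to 177 ± 22.9 CPM (-1.58 ± 0.23, adjusted p = 0.000231). Of 2200 genes, 350 were called, 191 higher and 159 lower, and 71 changed at least 2-fold. All 4 interferon gamma response genes rose (adjusted p = 1.67e-07 by camera, and adjusted p = 0.035 with an estimated correlation), among them Irgm2 by 1.03 ± 0.16 and Tgtp1 by 0.96 ± 0.16. Of 4 drug metabolism genes 3 rose and 1 fell: Aldh1a1 rose from 422 ± 42.2 to 756 ± 108 CPM (0.84 ± 0.12) and Cyp2c50 from 51.3 ± 7.14 to 83.0 ± 13.3 CPM (0.70 ± 0.11), and the call of Cyp2c29 (0.72 ± 0.20) was lost without mouse 15 (0.63) or mouse 17 (0.62), with a fit of the 2 groups and with no filter. Of 3 bile acid genes 2 rose and 1 was not called (adjusted p = 0.00176 by camera, and adjusted p = 0.0777 with an estimated correlation), Akr1d1 and the canalicular transporter Abcc2 (0.76 ± 0.13). Of 3 cell death genes 2 rose, and adjusted over the list alone 1 also fell. Of 3 CD40 and its signalling genes Fas rose (0.31 ± 0.10, adjusted p = 0.0389) and 2 were not called. The Fas call was lost with library totals, no filter or a fit of the 2 groups and without mouse 11, 12, 17 or 20, with values of 0.31, 0.27, 0.27 and 0.29. Of 3 microbial product sensing genes Nlrp3 fell from 17.5 ± 8.55 to 7.98 ± 2.44 CPM (-1.14 ± 0.32, adjusted p = 0.019), a call lost with a fit of the 2 groups and without mouse 14 (-0.98) or mouse 18 (-0.86). Of 3 chemokines Ccl3 fell from 9.12 ± 9.91 to 2.66 ± 1.10 CPM (-1.77 ± 0.52, adjusted p = 0.0268), a call lost with limma-voom (-1.07), with no filter, with a fit of the 2 groups and without mouse 11 (-1.66), 14 (-1.68), 15 (-1.62) or 18 (-0.88); adjusted over the list alone, 1 rose and 1 fell. Of 3 sinusoidal endothelial genes Stab1 fell (-0.89 ± 0.26, adjusted p = 0.0247), a call lost with a fit of the 2 groups and without any 1 of mice 13 to 18, with values of -0.83 to -0.70. Of 5 hepatocyte identity genes 1, Alb, rose (0.41 ± 0.13, adjusted p = 0.0292), a call lost without mouse 11 (0.42), 12 (0.36), 17 (0.33) or 18 (0.43). Of 3 gluconeogenesis and glycolysis genes Pcx fell (-0.47 ± 0.12, adjusted p = 0.0101) and 2 were not called. The median, mean and test differ in sign for the chemokines, gluconeogenesis and glycolysis, and proliferation lists. Among the largest changes, Smox fell from 146 ± 98.7 to 25.7 ± 4.40 CPM (-2.50 ± 0.35, adjusted p = 0.000166), the neutrophil surface protein gene Cd177 from 13.3 ± 11.2 to 2.67 ± 0.527 CPM (-2.30 ± 0.42, adjusted p = 0.000777, and -1.63 without mouse 18, the highest), the protease inhibitor A2m from 18.3 ± 10.4 to 3.86 ± 3.10 CPM (-2.25 ± 0.52) and Rps6ka2 from 6.67 ± 4.70 to 1.29 ± 0.580 CPM (-2.38 ± 0.42), and Ripk2 rose from 68.0 ± 19.8 to 199.8 ± 30.3 CPM (1.56 ± 0.15, adjusted p = 1.09e-06). With ABX, 25 genes were higher in both control and anti-CD40 mice, against 6.6 for independent lists, among them Cyp2c50, and 8 were lower in both, against 5.1, among them Cyp3a11. Among the called genes named here, the groups overlapped for Rps6ka2, A2m, Fas, Ccl3, Nlrp3, Stab1, Alb, Cyp2c29 and Pcx. All anti-CD40 mice with ABX and 1 without lay in plate column 4 and the other 4 in column 5. With plate column as a term the comparison rests on mice 11 to 15 against mouse 16 alone. Most of the genes named here then lost their calls, which the loss of mice or plate column could give. Without mouse 14 or 18 there were 225 and 230 calls, and without mice 14, 15, 19 and 20 there were 170, without Fas, Alb, Cyp2c29 and Pcx.

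**Figure D4:**
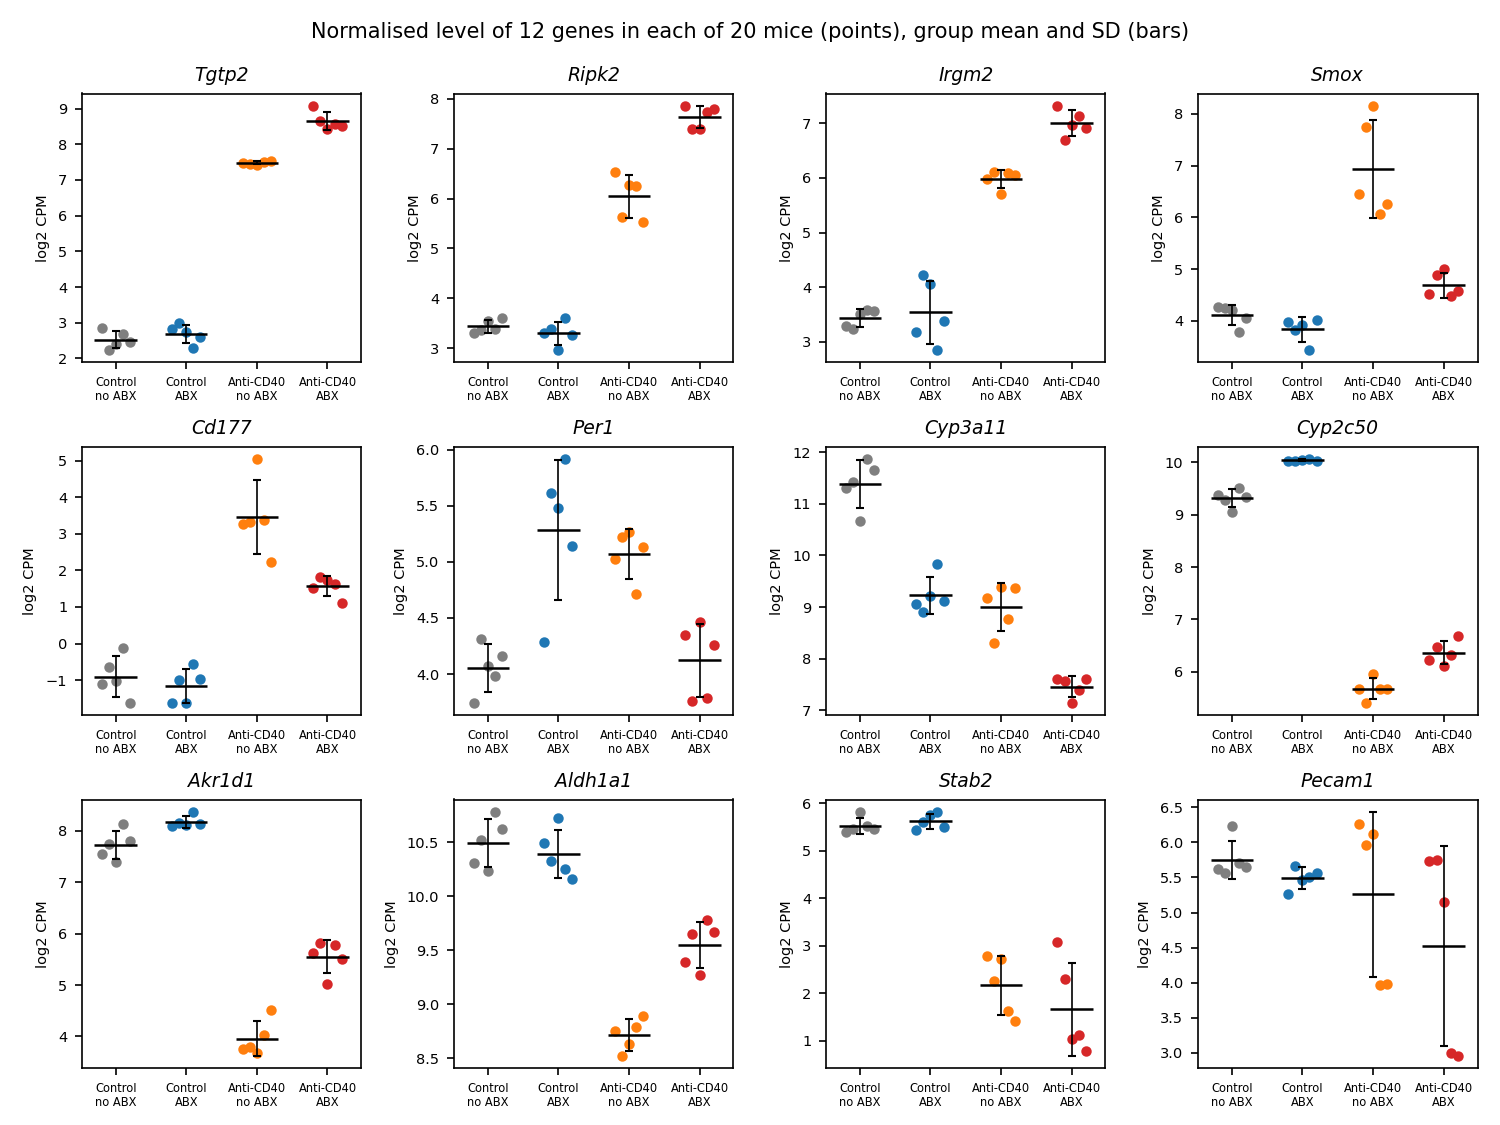
Normalised level (y axes, log2 CPM) of 12 genes in each of 20 mice (points), by group (x axes), with group means and SD (bars); scales differ between panels. Tgtp2 and Irgm2 are higher in every anti-CD40 mouse than in every control mouse, and Pecam1 spreads widely among anti-CD40 mice, from 7.4 to 76.9 CPM.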

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

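Chosen after the result was seen were the tests of plate column and of non-hepatocyte cells for the endothelial pattern. So were the use of plate column as a term for Per1 and the exact interval placed around both shares of genes for the ABX comparison. All checks without mice 14, 15, 19 and 20 were also chosen then. The other tests and their bounds were written before. The reading of the share of calls kept with both scalings departs from its written rule.

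The counts of called genes were set against 100 splits of the mice into groups of the same sizes, the real one included, and in each comparison only 1 split, the real one, gave as many. The real count and the highest of the other splits were 1333 and 554 for anti-CD40 without ABX, 1133 and 69 with ABX, 166 and 29 for the difference of the effects, 147 and 17 for ABX in control mice, and 350 and 120 for ABX in anti-CD40 mice. With 100 splits, chance in the grouping of the mice is thus unlikely for these 5 counts but not excluded. Every other split mixes the groups compared and so widens the spread within them. With effects as large as those of anti-CD40, fewer calls in the other splits were likely from the start.

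A value was singled out when 1 mouse stood apart from the other 4 of its group by more than 0.71 of the group's whole range. This held for 31 of 359 values tested. Chance would give about 1 in 20, or 18, for independent and normally distributed values. These values are not: those of 1 mouse move together, and some lie at the count floor. The 2 numbers therefore do not measure an excess. Mouse 8, a control without ABX, gave the most. Its mitochondrial share was 22.42% against 30.08% in the others (gap over range 0.747), and it stood apart in 8 genes, given with the gap over range: it was lowest for Abcc2 (0.865), Fads2 (0.762), Pitx3 (0.768) and Pygl (0.955) and highest for Cp (0.921), Lyz2 (0.767), Pecam1 (0.784) and Stab2 (0.716). Mouse 1, a control with ABX, was lowest for Baat (0.738), Cp (0.796) and Nfkbia (0.773) and highest for Gramd1b (0.826), Rps6ka2 (0.728) and Lrmda (1, the single mouse of its group with a count). Among other controls without ABX, mouse 9 was lowest for Atl1 (0.719), mouse 6 was lowest for Lrmda (0.824), and mouse 7 held the group's only count of Ly6i (1). Among other controls with ABX, mouse 2 was lowest for Ccnb2 (0.753), mouse 3 was lowest for Nfkb2 (0.723), and mouse 4 was highest for Akr1d1 (0.812) and Cyp2c50 (0.711). In anti-CD40 mice with ABX, mouse 11 was highest for Arrdc3 (1), mouse 12 for Fbln5 (0.904) and Syt15 (0.837), and mouse 13 for Ifih1 (0.732). Mouse 15 was highest for Ces4a (1) and lowest for Ccl24 (0.82), while mouse 14 was lowest for Crispld2 (0.736). Mouse 11 held the group's only count of Arrdc3, and mouse 15 its only counts of Ces4a. In anti-CD40 mice without ABX, mouse 17 was lowest for Alb (0.71) and mouse 20 for Ripk3 (0.717).

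The anti-CD40 effect differed between mice with and without ABX for 18 genes under the naming rule, by the test of the difference itself. The log2 difference, with ABX minus without, was positive for Ripk2 (1.68), Kcna2 (1.5), Slc16a12 (1.39), Tbx3 (1.39), Zbed3 (1.26), Akr1d1 (1.18), Tgtp2 (1.02), Aldh1a1 (0.95) and Fas (0.72), and for Lrmda (2.95), whose value rests on 1 count in control mice with ABX and 9 in those without. It was negative for Prr33 (-3.03), Rps6ka2 (-2.87), Atl1 (-2.36), Per1 (-2.28), Smox (-2.22), Adamtsl2 (-1.99), Gramd1b (-1.76) and Nfkbia (-0.81). The calls of 4 of these were lost when 1 mouse was left out: Nfkbia without any 1 of 12 mice (mice 2, 3, 4, 5, 8, 9, 10, 11, 13, 14, 16, 18; -0.80 to -0.72), Tbx3 without any 1 of 12 mice (mice 2, 4, 7, 8, 10, 13, 14, 15, 16, 17, 18, 19; 1.27 to 1.42), Gramd1b without any 1 of 12 mice (mice 1, 8, 9, 10, 11, 13, 14, 15, 16, 17, 18, 19; -1.82 to -1.15) and Lrmda without any 1 of 16 mice (mice 2, 3, 4, 5, 7, 8, 9, 10, 11, 13, 14, 15, 16, 17, 18, 20; 2.75 to 3). Without mouse 1 Lrmda stood at 4.42 and Gramd1b at -1.15. Without mice 14, 15, 19 and 20 the calls of Lrmda, Tbx3, Zbed3, Atl1 and Gramd1b were lost. With plate column as a term those of all these genes were lost. That term leaves mouse 16 alone for anti-CD40 without ABX, so the loss of mice could also give this. Plate column and ABX are therefore not told apart for these differences.

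Endothelial and matrix genes differed widely among anti-CD40 mice, with Pecam1 from 7.4 to 76.9 CPM and lowest in mice 14, 15, 19 and 20. Plate column as the cause is argued against, since the 4 anti-CD40 mice of column 5 alone spanned 21.6 units on the first component of the residuals, over the bound of 10. Depth is argued against by the totals of the anti-CD40 libraries, from 5053014 to 6211642 counted fragments. They are too close to give the log2 ratio of 3.38 between the highest and lowest Pecam1 levels. With all libraries thinned to 5053014 counts the ratio was 3.31, a test that with such totals could hardly have come out otherwise. A lower share of all non-hepatocyte cells stays open. In anti-CD40 mice without ABX the coefficient of variation was 62.9% for Pecam1 and 12.4% for the antigen-presentation gene H2-Aa, a ratio of 0.2 under the bound of 0.75. That of the myeloid gene Lyz2 was 49.4%, a ratio of 0.79 over the same bound, so the 2 genes of other cells disagree. A different loss of endothelial cells between treated mice, or a different piece of liver taken, may lie behind the pattern; the design gives no group for either, and no biological explanation was tested.

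The genes that differed with ABX among anti-CD40 mice were weighed against plate column and against a few genes taking most counts. Mouse 16, without ABX but in the plate column of the ABX mice, lay on the side of its own group for 231 of the 292 genes called without it, or 79.1% (exact binomial interval 74% to 83.6%); plate column predicted under 50% and the bound against it was over 75%, inside the interval, so with 1 library the plate column and ABX cannot be told apart. The other explanation predicted that under 80% of calls would hold with both RLE scaling and library totals. This prediction was met, since 260 of 350 did, or 74.3% (69.4% to 78.8%). But a shift of all genes ends calls near the threshold whatever its cause, a point missing from the rule written before. The share therefore cannot tell whether a few genes taking most counts lie behind the calls, and that explanation stays open. Both intervals treat genes as independent trials, which they are not, and that of mouse 16 covers no spread between mice. The effect of ABX itself stays open.

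Per1 was higher with ABX among control mice. A single mouse is argued against, since the smallest log2 fold change without any 1 control mouse was 1.16, over the bound of 0.67, with a largest adjusted p of 0.00816. The size of the change in column 3 argues against plate column as the whole cause, though the gene was not called there. Among the 8 control mice of column 3 the value was 1.33 ± 0.35, against 1.34 ± 0.22 in all 10. With plate column as a term it was 1.34 ± 0.28 at an adjusted p of 0.0176 by edgeR. That term, chosen after the result was seen, compares the same 8 mice, with a spread estimated from all groups. It is therefore no separate evidence. It left 74 of the 147 calls. In column 3 alone the edgeR call ended, at an adjusted p of 0.0997, with the fold almost the same and a larger SE from fewer mice. The rule written before asked there for a value over 0.67 and an adjusted p under 0.05. Its second part was not met. Over all alternatives to the log2 fold change of Per1, ABX against no ABX, control, the adjusted p ranged from 2.55e-07 to 0.0997. Per1 varies with time of day, and no time of sampling is given in the sources used here, so ABX and time of sampling cannot be told apart.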

How the results depend on the processing

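The stricter and wider attributions, the deposited features with no attribution and the fits without mice 14, 15, 19 and 20 were chosen after the data were seen; all other alternatives were planned. Comparisons are given in the order of the report. No paired analysis was possible because the groups share no mouse numbers. The counts of calls stayed within 1.5 times the main ones under RLE, upper-quartile and library-total scaling, both filters, DESeq2, limma-voom, fits of the 2 groups and the stricter and wider attributions. With plate column as a term they were 735, 690, 0, 77 and 5, and in plate column 3 alone 44 for the fourth. The deposited features gave 3136, 2747, 370, 310 and 759 of 5432 features, more because more units were tested; the stricter attribution gave 920, 767, 119, 107 and 262 of fewer genes. Without mice 14, 15, 19 and 20 they were 1231, 1025, 79, 130 and 170. Leaving out 1 library gave 1262 to 1349, 1047 to 1154, 88 to 194, 89 to 157 and 225 to 380. Camera called 6, 7, 1, 0 and 2 lists, 0, 3, 0, 0 and 1 with an estimated correlation, and fry 12, 11, 3, 0 and 5. Of 217 gene values under 1930 planned settings, 1781 kept direction and side of the threshold, 120 lost it, 12 gained it and 17 turned; leaving out 1 library these were 4152, 156, 17 and 15 of 4340, and under the added alternatives 543, 21, 2 and 4 of 570. Values that turned were not called as reported, except that of Asgr1 in the second comparison. With library totals these were, in the first, Pecam1 0.0869, Baat 0.17 and Ccnb2 0.0468; in the second, Asgr1 0.0956, Abcc2 0.11 and Baat 0.32; in the third, Cyp2c50 0.0858; in the fourth, Cyp2c29 -0.11. With plate column as a term they were Pecam1 0.60, Pcna -0.12 and Kif11 -0.26 in the first, Cyp2c29 -0.0739 in the third, Aldh1a1 0.0417 in the fourth, also 0.0361 in column 3 alone, and Nfkbia -0.16 in the fifth. Upper-quartile scaling turned Baat in the third (-0.000441) and limma-voom Cyp2c29 in the fourth (-0.0405). Without mice 14, 15, 19 and 20 Pecam1 was 0.33 in the first and 0.0536 in the second, and in the fifth Nfkbia -0.0634 and Cx3cl1 -0.14. Leaving out 1 library gave Pecam1 -0.44 to 0.0183, Ccnb2 -0.44 to 0.0177, Kif11 -0.0215 to 0.33 and Stab1 -0.0387 to 0.27 in the first, Cyp2c50 -0.10 to 0.0655 in the third, Cyp2c29 -0.0737 to 0.0968 in the fourth and Cx3cl1 -0.10 to 0.57 in the fifth. Except where fewer or more units or libraries were tested, the cause was not tested. Small changes were recovered less often. In simulations of ABX in control mice on 2074 genes, 45.2%, 84.5% and 98.6% of genes changed 1.5-fold, 2-fold and 4-fold were recovered. Depth, the spread between mice and the number of mice were not varied, so the limit was not traced to any of them.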

Other observations

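Chosen after the result was seen were the description of intervals shared by several genes and the choice of intervals given here. No explanation was tested on them. The intervals were fitted without plate column as a term. For the difference of the effects and for ABX in anti-CD40 mice, plate column and ABX are therefore not told apart here either.

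Intervals over the exons of 2 to 4 genes could not be attributed to 1 gene, so each value below belongs to the interval, and any of its genes may carry it. Of 1862 such intervals tested by edgeR, 1102 were called for anti-CD40 without ABX, 600 higher and 502 lower, and 981 with ABX, 508 higher and 473 lower. For the difference of the effects 144 were called, for ABX in control mice 110 and for ABX in anti-CD40 mice 282. Log2 fold changes of anti-CD40 are given without ABX and then with ABX. Several intervals over interferon-response genes were higher: Gbp5, Gbp7, Gbp3 and Gm43802 (4.27 ± 0.14 and 4.80 ± 0.14), Ifi44l and Ifi44 (4.83 ± 0.17 and 5.59 ± 0.18), and Psmb9 and Tap1, of antigen processing (3.15 ± 0.12 and 3.50 ± 0.13). So was that over Nlrc5, the MHC class I transactivator, and Cpne2 (2.14 ± 0.09 and 2.08 ± 0.09), that over Ciita, the MHC class II transactivator, and Dexi (3.88 ± 0.36 and 3.27 ± 0.33), and that over Zbp1, a nucleic acid sensor, and Pmepa1 (4.42 ± 0.14 and 4.84 ± 0.15). The interval over Ddx58 and Aco1 rose little (0.31 ± 0.06 and 0.45 ± 0.06), and that over Nos2, Ksr1 and Nf1 was not called (-0.17 ± 0.24 and 0.14 ± 0.23). The natural killer cell receptor genes Klre1, Klrd1 and Klrk1 share an interval that was higher as well (1.93 ± 0.22 and 2.23 ± 0.22). The interval over Hp, haptoglobin, with Dhodh, Txnl4b and Pkd1l3, took 2.52% ± 2.43 (SD, n = 5) of counts in control mice without ABX and 1.24% ± 0.144 with ABX, and 18.7% ± 1.39 and 17.6% ± 0.592 in anti-CD40 mice. Mouse 8 carries much of the first mean: its share was 6.86%, against 1.44% ± 0.211 in the other 4 control mice without ABX.

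Intervals over metabolic genes moved in both directions. Higher was that over Pfkl, a glycolytic enzyme, with 1810043G02Rik and Trpm2 (1.47 ± 0.12 and 0.64 ± 0.12). Others were lower. That over Acaa1b, a peroxisomal thiolase, with Slc22a13 and Oxsr1, stood at -4.56 ± 0.28 and -3.70 ± 0.28, that over Acaa2, Myo5b and Dym at -2.27 ± 0.12 and -2.37 ± 0.12, and that over Ppara, Wnt7b and AU022754 at -1.27 ± 0.13 and -1.70 ± 0.13. The interval over Abcb11, the bile salt export pump, and Gm13614 stood at -3.03 ± 0.12 and -2.06 ± 0.12, with a difference of the effects of 0.97 ± 0.16 (adjusted p = 0.00126), and was higher with ABX among anti-CD40 mice (1.10 ± 0.12). The interval over the neutrophil gelatinase gene Mmp9, Ctsa and Slc12a5 rose less with ABX (difference of the effects -1.57 ± 0.40, adjusted p = 0.0212), while for the interval over Mmp9, Zfp335 and Zfp335os the difference was not called (-0.78 ± 0.26, adjusted p = 0.0749). In control mice, ABX raised the intervals over the endoplasmic reticulum stress genes Herpud1, with 9330175E14Rik and Gm15889 (2.01 ± 0.26, adjusted p = 0.000322), and Hsp90b1, with Ttc41 and 1810014B01Rik (1.59 ± 0.24, adjusted p = 0.00064). The third stress-list interval, over Pdia4 and Zfp786, was not called (0.08 ± 0.18, adjusted p = 0.874). The difference of the anti-CD40 effects for the first 2 was -2.75 ± 0.39 and -2.31 ± 0.33. Most genes of the interferon, acute phase, bile acid and stress lists were not measured on their own, so the attributed genes speak for a small part of these lists.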
